A study of Homo sapiens with 12 samples.

How the data were processed

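RNA from cultured normal human bronchial epithelial cells, untreated or exposed to A. fumigatus spores, was sequenced at 2, 6 and 12 h, with 2 pools of 3 wells for each of 6 groups. Nothing in the sources used here says that the pools come from separate donors, so the p-values are not shown to measure spread between donors. They come from the authors' test. How far they reflect the spread between these pools, which may be technical, cannot be seen. Per the submitters' processing notes, Bowtie2 2.0.0, TopHat2 2.0.8, Cufflinks 2.0.1, Cuffdiff (no version) and the hg19 build were used. The annotation, the library normalization mode and the filters are not given in the sources used here. The authors deposited 3 tables per time, 9 in all: a full table, its significant genes and a final version of these.

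Per the file headers, the deposited tables hold 1 FPKM value for control and 1 for infected cells per gene. These values are taken here to be made by the authors from both pools of a group, which the headers do not say. The authors' log2 fold change is infected over control, recomputed here from the FPKM to within rounding. The deposited p-value of each gene equals the two-sided normal tail of the authors' test statistic, with a largest difference of 2.88e-06, and the q-value is the authors' adjustment of it. The standard error was therefore taken as the size of the log2 fold change over that of the statistic, and it is called implied. Genes with a q-value at or under 0.05 among those with test status OK in the authors' table were counted as called, higher and lower separately. Values per sample were not used here, since the tables hold group values, so no test on samples was run. Read depth is unknown: the tables hold no totals. A check for whole-read steps in low olfactory receptor values put 40.0 to 66.7% of them near a whole step (0.1 of it), against 37.5 to 42.9% for shuffled values, so no counts were derived.

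The tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Named genes had status OK, a q-value at or under 0.05, at least 1 FPKM in the higher group and no value of 0. They are the 8 largest increases and 8 largest decreases per time with protein-coding style symbols, up to 3 members of each of 31 fixed lists with a call, 17 fixed genes whatever their result, and up to 5 genes called in opposite directions at different times. Genes outside the rule are said to be chosen after their values were seen. Beyond the rule as written, rows with merged symbols were left out of the ranking, and 1 row per symbol (highest mean FPKM) was ranked. That displaced 6 rows: RAB10 (-0.84) and CTNNBIP1 (1.06) at 2 h, and UQCR11 (-1.01), ELAVL1 (-0.85) and RFX7 (-0.47) at 6 h, whose kept rows had 0.10, -0.05, -0.03, 0.12 and 0.20, and 1 that is not reported here. Sex-linked marker genes were left out of every ranking.

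Each fixed list was tested by a two-sided Fisher's exact test of called members against other tested genes with at least 1 FPKM, Benjamini-Hochberg adjusted over 170 tests. Members are not independent replicates. Differences of the infection effect between times were tested with a two-sided z test from the implied standard errors, Benjamini-Hochberg over genes. Calls at 2 times were compared with the number that independent lists would share, among genes with at least 1 FPKM at both times.

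The alternatives set in advance were a q threshold of 0.01, a floor of 1 FPKM, a log2 fold change of at least 1, recomputed Benjamini-Hochberg values, direction after centring on the median gene, 1 row per symbol, rows with no 0, the authors' shorter tables, a pseudocount of 1 FPKM and a wider list background. Chosen after seeing the data were a new test after centring, named rows only, implied standard errors multiplied by 2, and removal of the GC trend. The trend is the running median of log2 fold changes over 20 bins of gene GC content. GC content came from GENCODE 29 transcripts, which are on another build than the files, so only names, lengths and GC were used. Of 21515 symbols, 20321 matched a current or older symbol. Positions are 1-based, the start in the files plus 1. Some named genes share a locus with another row, so their reads may not be fully told apart from those of that row. Among them are ZNF750, DDIT3, CITED4, KIAA1199 and PFKFB3 at 2 h and CBX5 at 6 h.

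The programs were tested on simulated data made from the real tables with 200 genes changed. Noise was drawn with the implied standard errors that the test then used, so the recovery holds only if these errors are right. Of genes changed 1.5-fold, the test recovered 84% at 2 h (17471 genes), 88% at 6 h (17488) and 86% at 12 h (17158). Changes of 2-fold were recovered in 92, 98 and 92%, but 1.25-fold changes in only 46, 60 and 58%. The median fold of genes called higher in the authors' deposited table was 1.19 at 2 h, 1.17 at 6 h and 1.36 at 12 h. With a common shift of 0.4 on the log2 scale, 10689 of 16958 unchanged genes at 12 h were called as tested and 8 after centring. With a simulated GC trend, which was not fitted to the real one, 575 of 15442 unchanged genes at 6 h were called and 8 after its removal. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. KRT5 and other rows above the fragment limit of the authors' test were left out of tests, as were rows not tested by the authors.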

Results

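The deposited data describe gene expression in normal human bronchial epithelial (NHBE) cells, primary airway lining cells grown in culture, with and without spores of the mould Aspergillus fumigatus. The 12 RNA sequencing samples fall into 6 groups, untreated control and infected cells at 2, 6 and 12 h, with 2 pools per group and RNA from 3 wells in each pool. The deposited tables give 1 FPKM value (fragments scaled by transcript length and library size) per gene and group, so no value of a single pool and no standard deviation between pools can be given. The error given with a log2 fold change is the standard error implied by the authors' test statistic. Each table has 27023 rows, of which the authors tested 21684 at 2 h, 21715 at 6 h and 21277 at 12 h. No read totals are in the files, so the depth of each sample is unknown. Fold changes are infected over control, positions are in hg19, and a gene is said to rise or fall where its q-value in the authors' deposited table is at or under 0.05.

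The comparison at 2 h asks which host transcripts differ soon after contact with the spores. Inflammatory mediators and fast-responding transcription factors were higher in infected cells. IL8 (CXCL8), the chemokine that attracts neutrophils, on chromosome 4 at 74606223 to 74609433, rose from 2.79 to 8.81 FPKM, a log2 fold change of 1.66 with a standard error of 0.15. IL36G, an interleukin-1 family cytokine of epithelia, rose by 1.43 on the log2 scale (standard error 0.21), with a q-value of 1.34e-09 in the authors' deposited table. The transcription factors FOSB, EGR1 and ATF3 rose by 1.49, 1.21 and 0.99, and the epithelial differentiation regulators ZNF750 and OVOL1 each rose by 0.97. In the other direction, COL1A2, a chain of type I collagen on chromosome 7 at 94023873 to 94060544, went from 2.68 to 0.0541 FPKM, a log2 fold change of -5.63 with a standard error of 0.43, and COL1A1 had -0.72 with 0.06. The COL1A2 control level was 0.0409 FPKM at 6 h and 0.0767 FPKM at 12 h, so the 2 h control stood apart from the other controls. CITED4, a transcriptional co-activator, had a log2 fold change of -0.62, and the largest decreases also included SLC35G1 (-0.62), RTN4RL1 (-0.61), CTU1 (-0.56), KIAA1199 (-0.54) and OSBPL7 (-0.50). With 1 FPKM added to both groups, IL8 had 1.37, IL36G 1.05, FOSB 0.96 and OVOL1 0.73. COL1A2 then had -1.80, SLC35G1 -0.39, RTN4RL1 -0.36 and OSBPL7 -0.30.

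Of the lists fixed in advance, the immediate early and growth factor response stood out most at 2 h, with 17 of 25 measured members higher, 0 lower and 8 not past the test (20 higher when adjusted over the list alone; two-sided Fisher's exact test, adjusted p 7.99e-15). Among chemokines and cytokines, 8 of 23 rose and 0 fell (13 higher adjusted over the list alone; adjusted p 3.24e-04), including the interleukin-6 family cytokine LIF at 0.75 and CCL20, an attractant of dendritic cells and lymphocytes, at 0.60 with a standard error of 0.12. CXCL1, another neutrophil chemokine, rose by 0.37. In the NF-kB feedback and target list 9 of 18 rose (13 adjusted over the list alone; adjusted p 5.17e-06), among them the NF-kB subunit genes NFKB2 at 0.47 and NFKB1 at 0.40, and the feedback inhibitor TNFAIP3 at 0.28. The unfolded protein and amino acid stress list had 8 of 20 higher (9 adjusted over the list alone; adjusted p 1.59e-04), with DDIT3 at 0.77, the phosphatase subunit PPP1R15A at 0.73 and the glutathione-degrading enzyme CHAC1 at 0.62. Of p53 targets and apoptosis genes 7 of 20 rose (8 adjusted over the list alone; adjusted p 9.50e-04), with PMAIP1 at 0.41 and CDKN1A, an inhibitor of the cell cycle, at 0.34. Of cell junction genes 6 of 20 rose (8 adjusted over the list alone; adjusted p 0.00557), with the tight junction genes CLDN4 at 0.67 and OCLN at 0.47.

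Pattern recognition receptors and adaptors had 5 of 14 higher at 2 h (7 adjusted over the list alone; adjusted p 0.00659), with the adaptor gene TICAM1 at 0.34, and squamous differentiation had 5 of 22 higher (5 adjusted over the list alone; adjusted p 0.0402), with CRCT1 at 0.42. Both of these lists missed the threshold after the fold changes were centred on the median gene, with adjusted p 0.0555 and 0.500. Hypoxia and glycolysis had 0 of 27 higher and 3 lower (3 adjusted over the list alone; adjusted p 0.0119), which were the oxygen-sensing hydroxylases EGLN3 (-0.42) and EGLN1 (-0.27) and the glycolysis regulator PFKFB3 (-0.10). Of 4 measured fibroblast markers, 2 fell, COL1A1 and COL1A2 (3 adjusted over the list alone; adjusted p 0.00535). PTGS2, the inducible prostaglandin synthase, rose by 0.62 with a standard error of 0.07, and the plasminogen system genes SERPINB2 and PLAUR rose by 0.58 and 0.55. Over all genes, the authors' deposited table called 693 at 2 h, 581 higher and 112 lower, and 26 of them changed at least 2-fold. All 24 called rows without a gene name were lower.

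The comparison at 6 h asks how the host response stands when spores have been present longer. The genes that rose most included PTGS2, from 12.7 to 21.2 FPKM with a log2 fold change of 0.74 and a standard error of 0.07, and the cornified envelope gene LCE3E at 0.83 with 0.22. DUSP10, a phosphatase that acts on stress kinases, rose by 0.67, the heat shock gene HSPA6 by 0.63 and the tight junction gene CLDN1 by 0.51. The antimicrobial genes RNASE7 and PI3 rose by 0.37 and 0.24. HES6, a transcription regulator, had a log2 fold change of -0.62 with a standard error of 0.13, and the heterochromatin protein gene CBX5 had -0.55. With 1 FPKM added to both groups, DUSP10 had 0.45, HSPA6 0.39 and CBX5 -0.30. The secretory cell genes SPDEF and AGR2 had -0.32 and -0.21. At 6 h the authors' deposited table called 1793 genes, 1520 higher and 273 lower, and 23 changed at least 2-fold.

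The log2 fold change at 6 h followed the GC content of the gene. Across 10680 genes with a GC value, 84.1% of those at 1 FPKM or more, the Spearman correlation across genes, which are not independent replicates, was -0.73, against 0.11 at 2 h and -0.31 at 12 h. From the lowest to the highest of 10 bins of GC content the median log2 fold change at 6 h went from 0.21 to -0.10. Removing this trend and testing again with the implied standard errors called 124 genes, 76 higher and 48 lower, where the authors' deposited table called 1680 of the same rows. Of the 124, only 89 were called in the same direction as deposited. Each gene named so far for 6 h passed with the trend removed too, but PI3 did not pass after centring on the median gene. Genes that rose in the authors' deposited table but did not pass with the trend removed include CCL20 (0.81 before and 0.58 after, standard error 0.24), IL8 (0.46 and 0.23, standard error 0.14), IL33, an alarmin cytokine (0.48 and 0.25, standard error 0.08), CXCL1 (0.26 and 0.22, standard error 0.07) and TNFAIP3 (0.14 and 0.10, standard error 0.03). RMRP, the RNA of a ribonuclease complex, had -1.12 before and -1.02 after (standard error 0.32), and did not pass either. For CCL20, CXCL1 and RMRP the fold changed by less than its standard error, so the lost call does not show that the trend made up the difference.

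**Figure D1:**
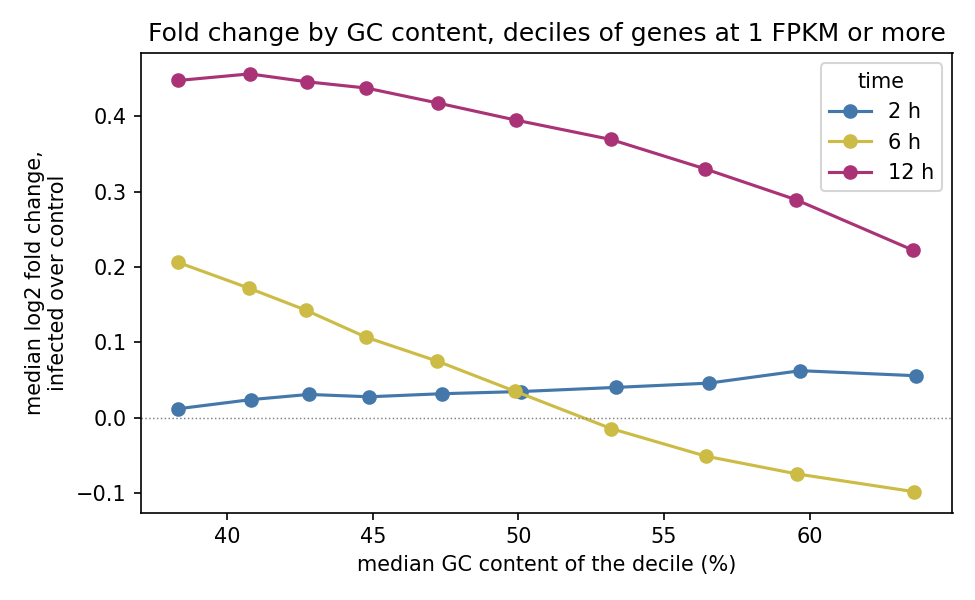
Median log2 fold change of infected over control by bin of gene GC content (10 bins of equal size) at 2, 6 and 12 h, for genes at 1 FPKM or more. At 6 h the median goes from 0.21 in the lowest bin to -0.10 in the highest.

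Few fixed lists passed Fisher's exact test at 6 h. The median of each list was also ranked among 10000 random lists of like mean expression. The highest percentiles were 99.99 for cell cycle, 99.94 for p53 targets and 99.9 for chemokines and cytokines, and the lowest was 0.38 for secretory cell markers. That ranking did not allow for GC content. With the GC trend removed, 0 cell cycle genes, 1 p53 target and 0 chemokines and cytokines were called higher. Cholesterol and fatty acid synthesis had 3 of 23 higher and 4 lower (4 lower adjusted over the list alone; adjusted p 0.0199), among them MVK (-0.23) and PMVK (-0.22), 2 enzymes of the mevalonate pathway, but 4 were lower after centring (adjusted p 0.205) and 1 with the GC trend removed (adjusted p 0.324). Of 4 secretory cell markers 2 fell, AGR2 and SPDEF (2 adjusted over the list alone; adjusted p 0.0306, with the GC trend removed 0.00129, and after centring 0.115). Ribosomal proteins had 2 of 75 higher, fewer than other genes (1 adjusted over the list alone; adjusted p 0.0455), 1 after centring (adjusted p 0.387) and 2 with the GC trend removed (adjusted p 0.369). The immediate early list had 6 of 24 higher (9 adjusted over the list alone; adjusted p 0.440), and with the GC trend removed 3 were higher, KLF4, DUSP1 and KLF6 (adjusted p 0.00802). After centring 3 were higher and 1 lower (adjusted p 0.562). The antimicrobial list had 3 of 14 higher (3 adjusted over the list alone; adjusted p 0.985), 2 with the trend removed (adjusted p 0.0398) and 2 after centring (adjusted p 0.606).

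The comparison at 12 h asks which host transcripts differ at the last time sampled. Genes of inflammation, cell junctions and wound repair were among those that rose most. IL36G rose from 0.720 to 9.33 FPKM, a log2 fold change of 3.70 with a standard error of 0.29, and IL8 rose from 2.14 to 23.0 FPKM, 3.43 with 0.15. OVOL1 rose by 3.15, ATF3 by 2.73, CLDN4 by 2.26, OCLN by 1.97, SERPINB2 by 2.05, PTGS2 by 2.04 and PLAUR by 2.00. CSF2, the growth factor of granulocytes and macrophages, rose by 2.03, and CXCL1, CCL20 and TNFAIP3 rose by 1.77, 1.55 and 1.52. For ATF3 and CCL20 the controls were lower at 12 h than at 2 h, at 0.626 against 5.08 and 3.09 against 10.1 FPKM. In infected cells ATF3 had 4.15 FPKM at 12 h and 10.1 at 2 h, and CCL20 9.06 and 15.3. Their larger effects at 12 h are therefore not higher levels in infected cells. IL8 was at 23.0 FPKM in infected cells at 12 h and 8.81 at 2 h. Each time was processed as its own table, so levels were not tested between times. The row with the largest increase, OPN1SW at 5.40 with a standard error of 1.28, had 0.0310 and 1.31 FPKM. It shares its locus with another row, so reads of the pair may not be fully told apart. The same holds for ATP1A1OS at 2.25, and RND1, a small GTPase gene, rose by 2.54. CHAC1 fell from 3.86 to 0.687 FPKM, a log2 fold change of -2.49 with a standard error of 0.27. The ribonuclease RNAs RMRP and RPPH1 had -1.54 and -1.13, the chemokine CXCL14 had -0.98, the growth factor FGF1 -0.88 and the Wnt receptor FZD2 -1.05. Fold changes of low genes, such as IL36G at 0.720 FPKM in controls, shrink when 1 FPKM is added to both groups. The values were then 1.17 for OPN1SW, 0.98 for RND1, 1.46 for ATP1A1OS, 1.66 for ATF3 and 1.07 for CSF2. For CHAC1 the value was -1.53, for FGF1 -0.41 and for FZD2 -0.47.

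Nearly all calls at 12 h were higher: the authors' deposited table called 9005 genes, 8883 higher and 122 lower, and 348 changed at least 2-fold. The median gene at 1 FPKM or more had a log2 fold change of 0.38, and 92.2% of such genes were above 0. At 2 h and 6 h the medians were 0.03 and 0.05. Centred on the median gene and tested again with the implied standard errors, 1853 genes were higher and 1665 lower at 12 h, and with the GC trend removed 1500 were higher and 1361 lower. The same centring left 340 higher and 166 lower at 2 h, and 741 higher and 670 lower at 6 h. Every gene named in the preceding paragraph passed in the same direction after centring and after removal of the GC trend. Relative to the median gene, IL8 rose by 3.04, IL36G by 3.31, CLDN4 by 1.87 and PTGS2 by 1.66, and CHAC1 had -2.87.

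**Figure D2:**
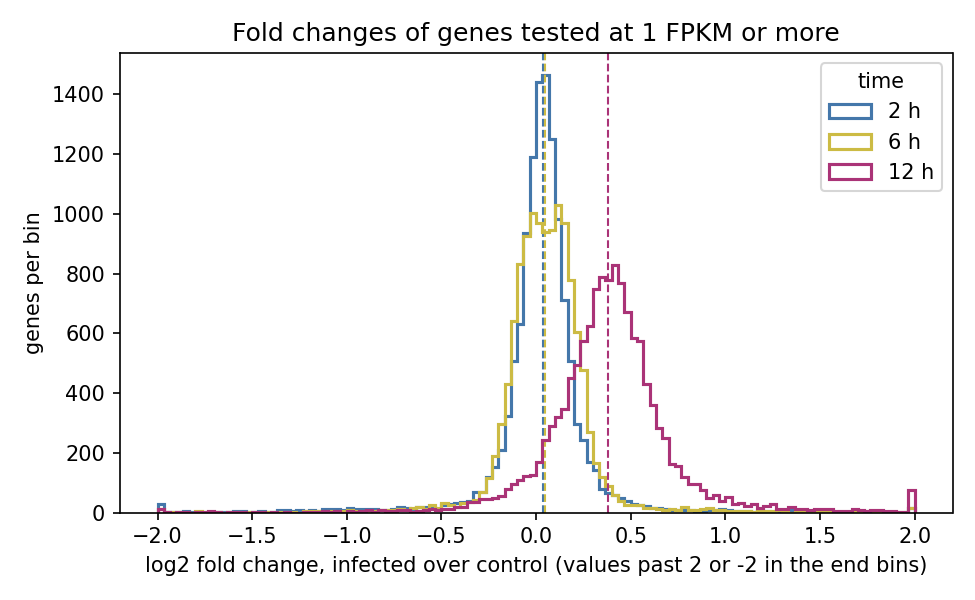
Distribution of log2 fold changes of infected over control at 2, 6 and 12 h, for genes tested by the authors with at least 1 FPKM. The 12 h distribution is centred near 0.38, and those at 2 h and 6 h are centred near 0.03 and 0.05.

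None of the 6 lists in this paragraph passed in the calls as deposited, where most genes rose, and the test after centring was chosen after that was seen. After centring, 13 of 22 chemokines and cytokines were higher than the median gene and 1 lower (adjusted p 5.70e-05), and 20 rose in the authors' deposited table (21 adjusted over the list alone; adjusted p 0.307). The immediate early list had 17 of 24 higher and 2 lower after centring (adjusted p 1.25e-07), with 22 higher as deposited (23 adjusted over the list alone; adjusted p 0.230), for example DUSP1 at 1.67 and DUSP5 at 1.30. Hypoxia and glycolysis, which had members lower at 2 h, had 16 of 29 higher and 0 lower after centring (adjusted p 1.86e-05; as deposited 25, adjusted p 0.525, and 26 adjusted over the list alone), including the lipase inhibitor ANGPTL4 at 1.58 and the vasodilator peptide gene ADM at 1.24. Cell junctions had 13 of 20 higher after centring and 0 lower (adjusted p 1.80e-05; as deposited 19, adjusted p 0.166, and 20 adjusted over the list alone), with CLDN1 at 1.63. Proteases and wound repair genes had 11 of 24 higher and 4 lower after centring (adjusted p 0.00484; as deposited 17 higher and 1 lower, adjusted p for higher 1, and 19 higher adjusted over the list alone). Squamous differentiation had 10 of 23 higher and 2 lower after centring (adjusted p 0.0114; as deposited 19, adjusted p 0.886, and 19 adjusted over the list alone), with the envelope cross-linking enzyme TGM1 at 1.33 and the envelope protein IVL at 1.15.

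Cell cycle genes lay below the median gene at 12 h. Of 32 members, 17 were lower after centring and 0 higher (adjusted p 5.36e-06), and as deposited 15 were higher and 2 lower (15 higher and 3 lower adjusted over the list alone; adjusted p for fewer higher 0.0264). The members lower as deposited were KIF20A, a motor protein of cell division, and the mitotic kinase PLK1, with -0.76 and -0.70 after centring, both chosen after their values were seen. Of p53 targets, 9 of 21 were lower and 5 higher after centring (adjusted p for lower 0.00895), but with the GC trend removed 7 were lower (adjusted p 0.0667). As deposited 14 rose and 0 fell (14 higher adjusted over the list alone; adjusted p 1 in both directions). Of 9 glucocorticoid response genes, 5 were lower after centring (adjusted p 0.0301), among them TSC22D3, which fell by 0.68 as deposited, but 4 with the GC trend removed (adjusted p 0.108), and as deposited 4 rose and 1 fell (the same counts adjusted over the list alone; adjusted p 0.321 in both directions). As deposited, 27 of 28 lysosome and uptake genes (adjusted p 0.0264; 28 adjusted over the list alone), 69 of 75 ribosomal protein genes (adjusted p 0.00101; 69) and 75 of 83 oxidative phosphorylation genes (adjusted p 0.00216; 79) rose. After centring 6, 3 and 11 of them were higher, so these rises were close to that of the median gene. Among 10000 random lists of like mean expression their medians lay at percentiles 28.9, 13.7 and 1.63. Set against genes of like expression, these lists therefore did not rise more. Of 23 histone genes 6 rose as deposited (5 adjusted over the list alone), fewer than among other genes (adjusted p 1.95e-04), and 0 after centring (adjusted p 0.206).

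**Figure D3:**
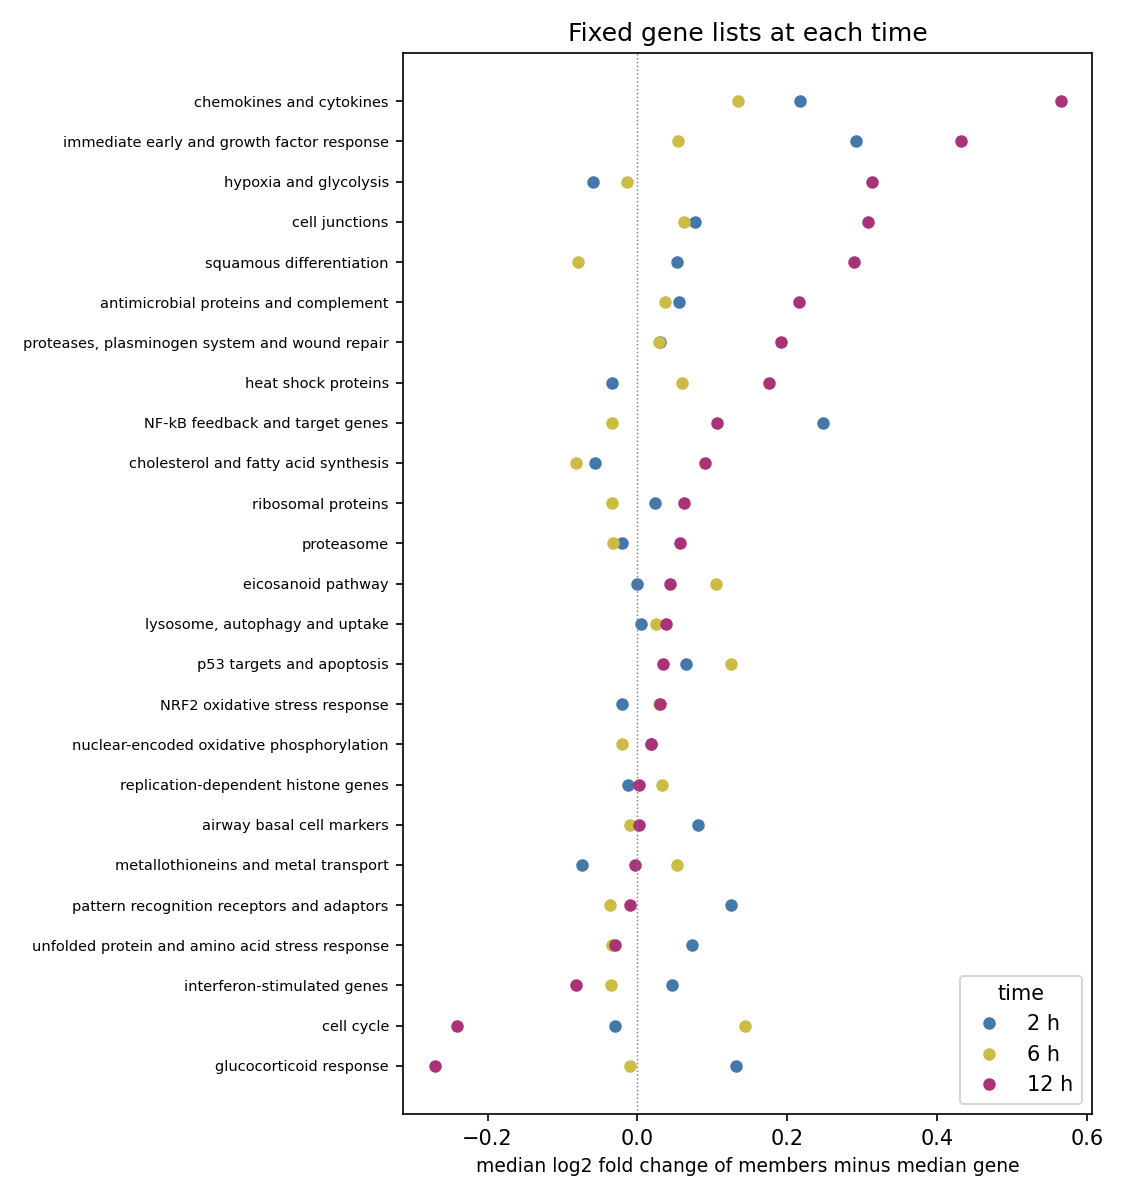
Fixed gene lists at 2, 6 and 12 h by the median log2 fold change of measured members relative to the median gene, with lists of few members left out. Cell cycle members have a median of -0.24 at 12 h, which is 0.14 as deposited.

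In all, 170 list tests were adjusted together, and 5 passed at 12 h in the calls as deposited, which were cell cycle (fewer higher), lysosome and uptake, ribosomal protein, oxidative phosphorylation and histone genes. At 12 h, 13 of 18 NF-kB genes rose as deposited (14 adjusted over the list alone) and 6 were higher after centring (adjusted p 0.226). Interferon-stimulated genes had 11 of 21 higher as deposited (11 adjusted over the list alone) and 1 higher after centring, and NRF2 oxidative stress genes had 21 of 23 (21 adjusted over the list alone) and 1. Of 15 heat shock genes 14 rose as deposited (14 adjusted over the list alone) and 4 were higher after centring. Metallothioneins and metal transport genes had 10 of 13 higher as deposited (11 adjusted over the list alone) and 1 after centring, and proteasome genes had 33 of 36 (33 adjusted over the list alone) and 3. Airway basal cell markers had 7 of 14 higher as deposited (7 adjusted over the list alone) and 2 after centring, and eicosanoid genes had 8 of 9 (9 adjusted over the list alone) and 1. The ciliated cell markers CAPS and DNAAF1 were the only 2 at 1 FPKM or more, and neither was called. No endothelial marker reached 1 FPKM in a tested row at any time, and 1 leukocyte marker, CD68, did so at 6 h with 1.03 FPKM in infected cells. These 3 genes were chosen after their values were seen. Of the genes fixed in advance, ICAM1, HMOX1, S100A8, TLR2, IFIT1, NFKBIA, IL6, GAPDH and ACTB were not called at 2 h or 6 h. NFKBIA rose by 0.81 at 12 h, 0.43 after centring. S100A8, HMOX1, ICAM1 and IL6 rose at 12 h as deposited but did not pass after centring. S100A8 went from 0.55 to 0.16 (standard error 0.07), HMOX1 from 0.64 to 0.26 (0.19) and ICAM1 from 0.54 to 0.15 (0.19). IL6 went from 2.43 to 2.04 with a standard error of 0.96, at 0.0971 and 0.521 FPKM (0.47 with 1 FPKM added to both groups), so its lost call does not show that the rise was the common shift. ICAM1 had 0.28 before centring with 1 FPKM added. KRT5 exceeded the fragment limit of the authors' test, so its listed values were not used here. DEFB4A was listed at 0 in infected cells at 2 h and in both groups at 6 h and 12 h, and MUC5AC and the mitochondrial-encoded mRNAs had no row.

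The infection effect was compared between times with a z test on the difference of log2 fold changes. It differed between 6 h and 2 h for 806 genes, 802 after centring and 186 with the GC trend removed. For 12 h against 2 h the counts were 6750, 1535 and 1034, and for 12 h against 6 h 6851, 1543 and 1439. The IL8 effect was smaller at 6 h than at 2 h, with a log2 difference of -1.20 and a standard error of 0.20, and larger at 12 h than at 6 h, with a difference of 2.97 and a standard error of 0.20. CHAC1 turned from higher at 2 h to lower at 12 h, with a difference of -3.12 and a standard error of 0.31. AGR2, which fell at 6 h, rose at 12 h, with a difference of 1.42 and a standard error of 0.10. The AGR2 control was at 42.9 FPKM at 6 h and 21.4 at 12 h, and infected cells had 37.0 and 49.4. Of 32 immediate early genes compared, 9 had a smaller effect at 6 h than at 2 h and 0 a larger one, and of 31 compared between 12 h and 6 h, 14 had a larger effect at 12 h and 2 a smaller one after centring.

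**Figure D4:**
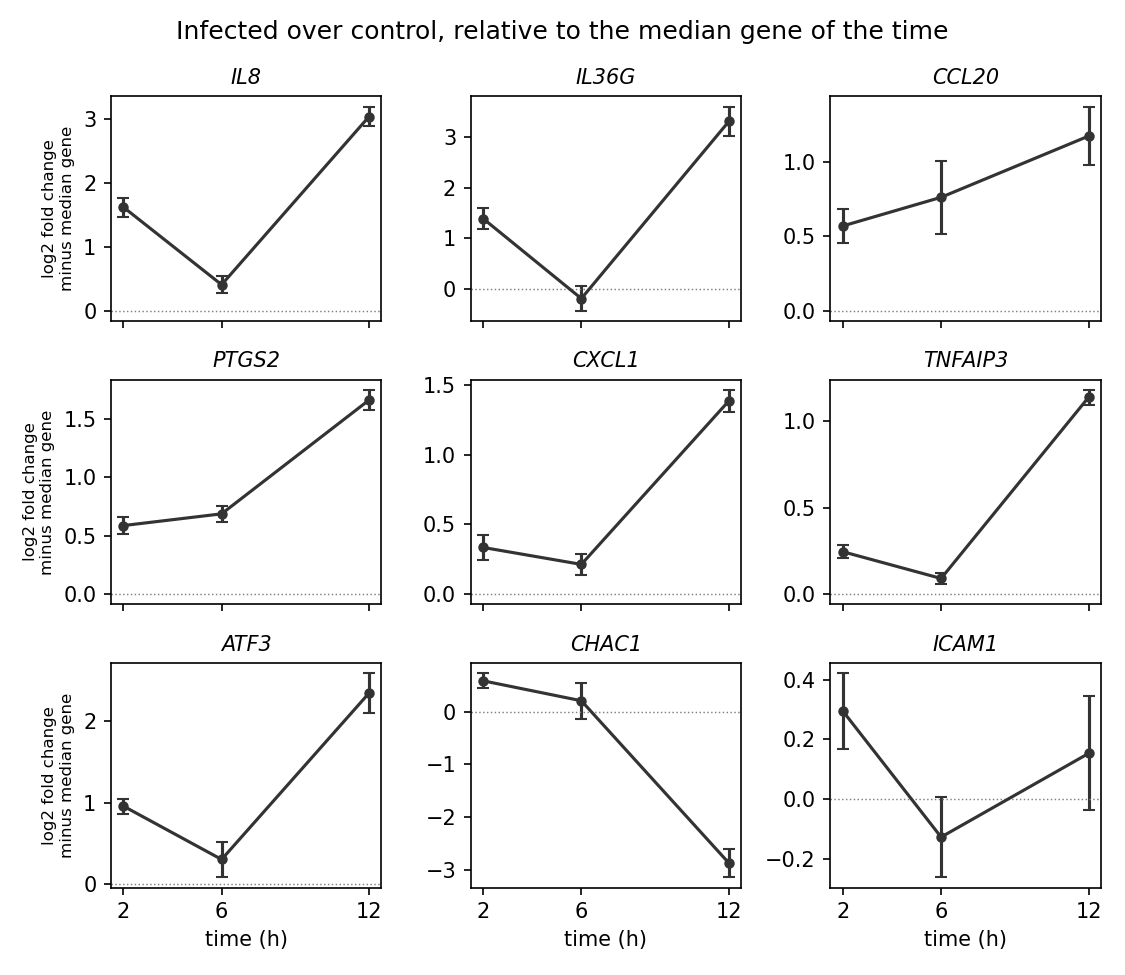
Log2 fold change of infected over control relative to the median gene at 2, 6 and 12 h for 9 genes. Bars are the standard error implied by the authors' test statistic, and the vertical scale differs between genes; IL8 has 1.62 at 2 h, 0.41 at 6 h and 3.04 at 12 h.

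Between 2 h and 12 h, 512 genes were higher at both times in the authors' deposited table, and 10 were lower at both. Low genes are seldom called at any time, so the number that independent lists would share is given for genes at 1 FPKM or more at both times. Among these, 509 were higher at 2 h and 12 h (392 for independent lists), 137 at 2 h and 6 h (67.5) and 1422 at 6 h and 12 h (1023). With the GC trend removed they were 209 (43.1), 26 (2.21) and 49 (10.0). Each time has its own control pools. The Spearman correlation of log2 fold changes across genes was 0.20 between 2 h and 12 h, 0.04 between 2 h and 6 h, and 0.30 between 6 h and 12 h. With the GC trend removed these were 0.29, 0.12 and 0.12. At all 3 times, 132 genes were higher in the authors' deposited table, and 354 were higher at 2 h and 12 h but not called at 6 h.

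Control levels are given side by side without a test, since each time was processed as its own table. The median control level of 29 cell cycle genes was 4.80 FPKM at 2 h, 5.89 at 6 h and 17.2 at 12 h, and the median log2 change of their control levels from 2 h was 0.26 at 6 h and 1.74 at 12 h. For 20 chemokines and cytokines the levels were 7.92, 5.47 and 2.95 FPKM, but the median change per gene was -0.13 and -0.36. Unfolded protein and amino acid stress genes had 53.1, 29.2 and 20.5 FPKM, with median changes of -0.56 and -0.58. Hypoxia and glycolysis genes had 68.2, 108 and 78.5 FPKM, with 0.29 and 0.36.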

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

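The scaling test in the next paragraph and the test of COL1A1 apart from the other collagen genes were chosen only after the result was seen. So were the 95% limits that decide the immediate early test, its wider set of members, and the correlations of GC content with changes between times. The same holds for each value after centring and retesting or with the GC trend removed. The other tests of explanations were written before their results were seen, the GC test after the trend itself was known.

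Nearly all called genes were higher in infected cells at 12 h. A single scaling difference between the 12 h libraries may account for the common part. The largest distance of the median of an expression bin (10 bins) from the overall median was 0.10 on the log2 scale. The interquartile range was 1.40 times that at 6 h. The shift was not even: bin medians ranged from 0.28 to 0.46 by expression, and went from 0.45 in the lowest to 0.22 in the highest bin of GC content. A single factor would not give these differences between bins. The estimated share of mapped fragments in named genes was 1.38 times the control value, but the median shift alone gives 1.30, so that test decides nothing. Fewer structural RNA fragments could not be judged: RMRP (-1.54), RPPH1 (-1.13), MIR663A (-1.21) and the merged row of ANKRD30BL and MIR663B (-0.44) fell at 12 h but were left out of the test because they had been seen to fall, and the 1 other gene tested, SCARNA12, had 0.94 (q-value 0.160). A real rise of most transcripts in infected cells was not measured by these values. FPKM is scaled by library size, so a rise shared by all transcripts would cancel in it. How the libraries were normalized is not given in the sources used here, so such a rise is neither shown nor excluded. A single scaling difference does not account for genes that pass after centring. Whether a rise that differs in size between genes does so was not tested.

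The log2 fold change at 6 h followed the GC content of the gene (Spearman correlation -0.73). A library effect tied to GC content may account for this: with genes split into 3 equal sets by GC content, the median of the lowest set was 0.24 above that of the highest on the log2 scale, and in the expression bin (10 bins) with the smallest difference it was still 81.7% of that. The correlation of GC content with the log2 change from 2 h to 6 h was 0.02 in controls and -0.22 in infected cells. From 2 h to 12 h it was -0.04 in controls and -0.21 in infected cells, and from 6 h to 12 h -0.12 and -0.03. In infected cells the shift from 2 h was thus about the same at 6 h and 12 h, so it is not particular to 6 h. A response of the cells that goes with GC content stays open, since the files hold 1 value per group and the libraries of a group cannot be compared with each other. Calls at 6 h that did not pass with the trend removed are therefore not shown to be responses to infection.

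Collagen transcripts were higher in the 2 h controls than in 2 h infected cells. Infection lowering COL1A2 and COL3A1 is argued against by the other controls, where COL1A2 reached at most 2.87% and COL3A1, in a row merged with MIR3606, at most 0.459% of the 2 h control level. Infection lowering COL1A1 stays open, since it was at 12.7, 5.54 and 8.48 FPKM in the controls and fell again at 12 h (log2 fold change -0.54, standard error 0.06; -0.92 after centring), but not at 6 h (0.06, standard error 0.06). Fibroblasts in a 2 h control pool may be the source, and the median log2 fold change of 4 other fibroblast markers, -0.0044, met the bound set in advance against it, but that bound was wrong, because FBLN1 and POSTN were above the COL1A2 gap of 2.62 FPKM in the 6 h and 12 h controls too, which would hide a small share. Of 10 fibroblast markers with a row of their own, 8 had a log2 fold change under 0 at 2 h but only 3 were called. These were COL1A2, COL1A1 and DCN, at 2.68, 12.7 and 0.658 FPKM in the 2 h control, and DCN had -4.49 (standard error 1.08). The merged row of COL3A1, outside this count, had -6.35 (standard error 0.76) and was called too. COL6A3 (-3.11) and PDGFRB (-3.16) were near 0 FPKM and not called, and THY1 (0.22) and FBLN1 (0.13) were above 0. Fibroblasts as the source therefore cannot be told apart from others in the data.

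Genes of the immediate early list were higher at 2 h and again at 12 h. The median centred effect of the 17 members called at 2 h was at 6 h 18.0% of that at 2 h, under the bound of 25% set in advance, but drawing members with replacement gave 95% limits of 3.48% to 38.9%, and members chosen by their 2 h calls favour a smaller effect at 6 h. Among all 24 members at 1 FPKM or more at both times it was 19.4% and, with the GC trend removed, 30.5%, with 95% limits of 3.68% to 43.5% and 10.1% to 55.4%. Members of a list are not independent, so all these limits reflect the choice of genes and not the spread between pools. Of these 24, 8 had a smaller effect at 6 h than at 2 h and 0 a larger one (6 and 0 with the GC trend removed), so one sustained response with a weaker effect at 6 h cannot be told apart from separate ones. Whether the later rise is a second response to the fungus, for example to its growth, was not tested.

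The infection effect differed between times for 806 genes (6 h against 2 h), 6750 (12 h against 2 h) and 6851 (12 h against 6 h) by the z test, and for 802, 1535 and 1543 after centring. The named genes that follow also differed after centring and, except where said, with the GC trend removed. AGR2 differed by 1.37 (12 h minus 2 h) and 1.42 (12 h minus 6 h). ANGPTL4 differed by -0.35 (6 h minus 2 h), 1.43 (12 h minus 2 h) and 1.77 (12 h minus 6 h), and the first was -0.19 with an adjusted p of 0.371 when the GC trend was removed. CDH6 differed by 0.77, 1.62 and 0.86 in the same order, and the last was 0.52 after centring and 0.55 with the GC trend removed. CHAC1 differed by -3.12 (12 h minus 2 h) and -2.75 (12 h minus 6 h), and CLGN by 1.72 and 1.29. In that order CXCL1 differed by 1.40 and 1.51, NFKBIA by 0.78 and 0.78 (0.43 and 0.45 after centring, 0.50 and 0.40 with the GC trend removed), PTGS2 by 1.42 and 1.31, and TNFAIP3 by 1.24 and 1.38. IL8 differed by -1.20 (6 h minus 2 h), 1.77 (12 h minus 2 h) and 2.97 (12 h minus 6 h).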

How the results depend on the processing

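No paired analysis was possible because the tables hold group values, so pools cannot be paired. Leaving out each replicate, a replicate block, tests on counts and tests on FPKM per sample were not run, for the same reason. Depth is unknown, so its limits cannot be stated. Where no reason is given the cause was not tested. Stricter thresholds call fewer genes by construction.

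At a q-value of 0.01, genes called at 2 h numbered 430 (genes higher at 2 h 368, lower 62), genes called at 6 h 1044 (genes higher at 6 h 915, lower 129) and genes lower at 12 h 71. With a log2 fold change of at least 1 they were 26 (7, 19), 23 (14, 9) and 348 (329, 19). These follow from the threshold. Benjamini-Hochberg over the 3 times together gave 1166 (933, 233) at 2 h.

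With calls kept and direction taken after centring, genes higher at 12 h numbered 5802 and genes lower at 12 h 3190. Tested again after centring, a test chosen after seeing the data like those after it in this paragraph, 340 were higher at 2 h, 741 higher and 670 lower at 6 h, and genes called at 12 h numbered 3518 (1853, 1665). This follows from subtracting the median. With the GC trend removed the calls were 456 (320 higher) at 2 h, 124 (76, 48) at 6 h and 2861 (1500, 1361) at 12 h, over fewer rows. Of these, 397, 89 and 1608 were called in the same direction as deposited. With the standard error doubled, the calls were 53 (47, 6), 30 (29, 1) and 5129 (5116, 13).

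Of the fixed list tests at 6 h, 3 passed as deposited, 1 at a q-value of 0.01 and 1 after centring, which was p53 targets with 6 of 19 higher (adjusted p 0.00895) but 1 with the GC trend removed (adjusted p 0.422). At 12 h, 5 passed as deposited, 13 against all genes tested, 11 after centring and 8 with the GC trend removed. FBLN1 at 12 h turned to -0.13 after centring and -0.038 with the GC trend removed. The odds ratio of p53 targets lower at 12 h turned to 4.90 after centring, and that of proteases higher at 12 h to 4.72 and, with the GC trend removed, 4.49. Ribosomal proteins higher at 12 h turned to 0.23 and 0.26, and oxidative phosphorylation higher at 12 h to 0.85 and 0.76. Ribosomal proteins higher at 6 h turned to 3.83 with the GC trend removed. The cause was not tested.

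The change in the infection effect between times, 6 h against 2 h, passed for 400 genes at an adjusted p of 0.01, 186 with the GC trend removed and 5 with the standard error doubled. For the change in the infection effect between times, 12 h against 2 h, the counts were 1535 after centring, 1034 with the GC trend removed and 1579 with the standard error doubled, and for the change in the infection effect between times, 12 h against 6 h, 1543, 1439 and 1578.

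At a q-value of 0.01, genes higher at both times were 70 (2 h and 6 h), 328 (2 h and 12 h) and 867 (6 h and 12 h), lower at both 6 (2 h and 12 h) and 4 (6 h and 12 h), and opposite 16, 28 and 94. With the GC trend removed they were 26, 210 and 49 higher, 43 and 13 lower, and opposite 1 (2 h and 6 h) and 18 (6 h and 12 h). Among genes at 1 FPKM or more, higher at both times were 26, 209 and 49.

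Among single genes named at a time, centring left 153 results within their standard error of the value as deposited and moved 116 beyond it. Removing the GC trend left 113 and moved 153. A pseudocount of 1 FPKM left 292 gene and list values and moved 59. Of the named called genes, 58 of 71 at 2 h, 65 of 77 at 6 h and 70 of 98 at 12 h passed after centring, and 60 of 71, 24 of 76 and 69 of 98 with the GC trend removed.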

Other observations

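The final version of the authors' tables leaves out the called genes whose p-value is listed as 0. It lists 650 genes at 2 h, 1767 at 6 h and 7121 at 12 h, and the 43, 26 and 1884 genes missing from it are the ones with a p-value of 0. IL8 is missing from it at 2 h and 12 h, and so are EGR1 and ATF3 at 2 h and IL36G, CXCL1 and PTGS2 at 12 h. A count or gene list taken from the final version would lack them.

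The structural RNAs RMRP and RPPH1 were lower in infected cells than in controls at 12 h, at 5.16 against 15.0 and 2.96 against 6.47 FPKM. The log2 fold changes of RMRP and RPPH1 were -1.12 and -0.55 at 6 h and -0.58 and -0.49 at 2 h. The 12 h controls stood above the others: RMRP had 6.25 and 5.79 FPKM in the 2 h and 6 h controls, and RPPH1 3.75 and 3.01. Infected cells had 4.19 and 2.67 FPKM of RMRP at 2 h and 6 h, and 2.68 and 2.06 of RPPH1. The larger difference at 12 h thus goes with higher controls, not with a lower level in infected cells.

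Some genes were called in opposite directions at different times. Over all rows these were 43 for 2 h and 6 h, 62 for 2 h and 12 h and 188 for 6 h and 12 h. Among genes at 1 FPKM or more at both times they were 43 (24.3 for independent lists), 57 (73.6) and 185 (193). With the GC trend removed as well, they were 1 (2.13), 48 (53.8) and 18 (14.3). AGR2, a gene of secretory cells, fell by 0.21 at 6 h and rose by 1.21 at 12 h. CLGN, a chaperone, and CDH6, a cadherin, fell by 0.43 and 0.47 at 2 h and rose by 1.29 and 1.15 at 12 h, but CLGN rose by 0.79 with 1 FPKM added to both groups. These 3 genes kept both calls after centring and with the GC trend removed.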
